A study of Homo sapiens with 12 samples.

How the data were processed

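RNA from 12 samples of HepG2 cells, a human hepatoma line used as a model of hepatocytes, was measured on single-colour Affymetrix arrays with whole-transcript probe sets. They formed 4 groups of 3 arrays: cells carrying a non-target control and cells with knockdown of HIF-1α, each either left uninfected or infected with Staphylococcus aureus for 4 h at a multiplicity of infection of 20. HIF-1α, encoded by HIF1A, is the oxygen-regulated subunit of a transcription factor. The labels describe the second line both as a knockdown and with a sign for gene loss, and it is called the knockdown line here. Groups were taken from the sample labels. The labels do not say whether the 3 samples of a group came from separate experiments, so p-values measure only the spread between these samples, which may be technical.

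The authors deposited 1 table of log2 values per probe set. The scale was taken from the values. The submitters' processing notes name GCOS version 1.1.1.052, and the method of summarisation and normalization is not given in the sources used here. Median log2 signal ranged from 5.29 to 5.38 over the 12 arrays, so the deposited values were used as they stood, without further normalization. Every infected array had a lower median (5.29 to 5.34) than every uninfected array (5.35 to 5.38), so an offset of scale cannot be told apart from infection. Signals of different probe sets were not set against each other. A normalization that forces a near-common distribution on all arrays would hide a change shared by most genes.

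The table held 33297 probe sets. In the platform annotation 19460 had exactly 1 gene symbol, 1754 had several and 12083 had none. Symbols were brought up to date through the Entrez identifier, which was present in the RefSeq gene table of assembly GCF_000001405.40 for 19429 probe sets. Each gene was represented by the probe set with the highest mean log2 signal over all 12 arrays, which gave 18417 genes. No coordinates are given, because the genome build of the array design is not given in the sources used here. No detection calls were used. As a reference for background chosen after the data were seen, the 361 olfactory receptor genes had a median log2 signal of 3.42 and a 95th percentile of 4.64, and 12872 genes had a mean above that percentile.

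All 12 arrays entered a linear model of the 4 group means in limma 3.58.1 under R 4.3.3, with moderated variances and neither a trend nor robust estimation. The comparisons were infected minus uninfected cells within each line, the difference of these responses (knockdown minus non-target), and knockdown minus non-target within uninfected and within infected cells. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Fold changes were computed from log2 differences, and errors after ± are standard errors of the model with n = 3 arrays per group unless stated otherwise. The number of arrays limits the precision: the median standard error was 0.10 on the log2 scale for a comparison of 2 groups and 0.14 for the difference of responses. On data simulated from these arrays, limma at adjusted p 0.05 recovered 80.6% of genes changed 1.5-fold, 98.5% of genes changed 2-fold and 100% of genes changed 3-fold for infection of non-target cells among 18417 genes, and 6.53% of its calls were unchanged genes. For the difference of responses the shares recovered were 46.3%, 89.6% and 100%, and 8.19% of the calls were unchanged genes. The simulation was run once, with independent normal noise and 1 spread per gene on all arrays. The real arrays had unequal weights (0.286 to 3.17), so these shares may be too favourable.

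Before the data were examined, 23 gene lists with 500 genes were fixed, of which 461 genes were measured; the others were not analysed here. Lists were tested with limma's camera with a preset correlation of 0.01, again with an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera compares the genes of a list with all other genes. FUT11 and NDUFA4 were first counted as not measured because their current symbols are POFUT4 and COXFA4. They were matched through their older symbols only after results had been seen, and values of both lists without them are in the closing section. The genes named were also fixed by a rule: HIF1A; per comparison the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose groups did not overlap (no such condition for the difference of responses); and up to 3 called members of each list with at least 2. XIST and Y-linked genes were left out, while X-linked genes such as TSPAN7 were kept. Genes outside the rule are named as members of small counts or chosen after their values were seen, as said there. The alternatives fixed beforehand were the replicate number as a block, fits on the 6 arrays compared, a trended and robust variance, array weights, quantile normalization, median centring, the brighter part of the probe sets, the mean of or all probe sets of a gene, stricter thresholds, and leaving out each array. Pseudocounts were planned only for linear values and were not used.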

Results

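The transcriptome of HepG2 cells was measured in 12 samples: non-target control cells and HIF-1α knockdown cells, each uninfected or infected with S. aureus for 4 h, with 3 arrays per group. The design addressed how infection changes gene expression in these cells and how much of that response differs when HIF-1α is depleted. Median log2 signal per array was between 5.29 and 5.38. The first principal component took 24.6% of the variance and the second 24.0%. Knockdown uninfected replicate 1 and knockdown infected replicate 3 stood apart from their groups, with limma array weights of 0.286 and 0.407. Counts without both arrays are given below as an alternative chosen after these weights were seen.

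HIF1A, the targeted gene, was lower in every knockdown array than in every non-target array. Its single probe set (7974851) read 10.40, 10.57 and 10.42 in the non-target uninfected arrays and 10.59, 10.59 and 10.39 in the non-target infected arrays. The knockdown uninfected arrays read 7.79, 8.07 and 7.95, and the knockdown infected arrays 7.47, 7.54 and 7.01. HIF1A was thus 5.75-fold lower in uninfected knockdown cells (log2 difference -2.52 ± 0.12, limma with Benjamini-Hochberg adjusted p = 1.5e-08) and 9.09-fold lower in infected knockdown cells (-3.18 ± 0.12, adjusted p = 4.3e-10). Infection gave a HIF1A change of 0.06 ± 0.12 in non-target cells (adjusted p = 0.87). In knockdown cells HIF1A fell 1.52-fold (-0.60 ± 0.12, adjusted p = 0.017), a call that was lost without knockdown uninfected replicate 2 (-0.53, adjusted p = 0.086), knockdown uninfected replicate 3 (-0.59, adjusted p = 0.058) or knockdown infected replicate 3 (-0.43, adjusted p = 0.054). It was also lost in a fit on the 6 arrays compared (adjusted p = 0.13) and when all probe sets were tested (adjusted p = 0.061). The difference between the HIF1A responses did not pass the threshold (-0.66 ± 0.17, adjusted p = 0.42).

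**Figure D1:**
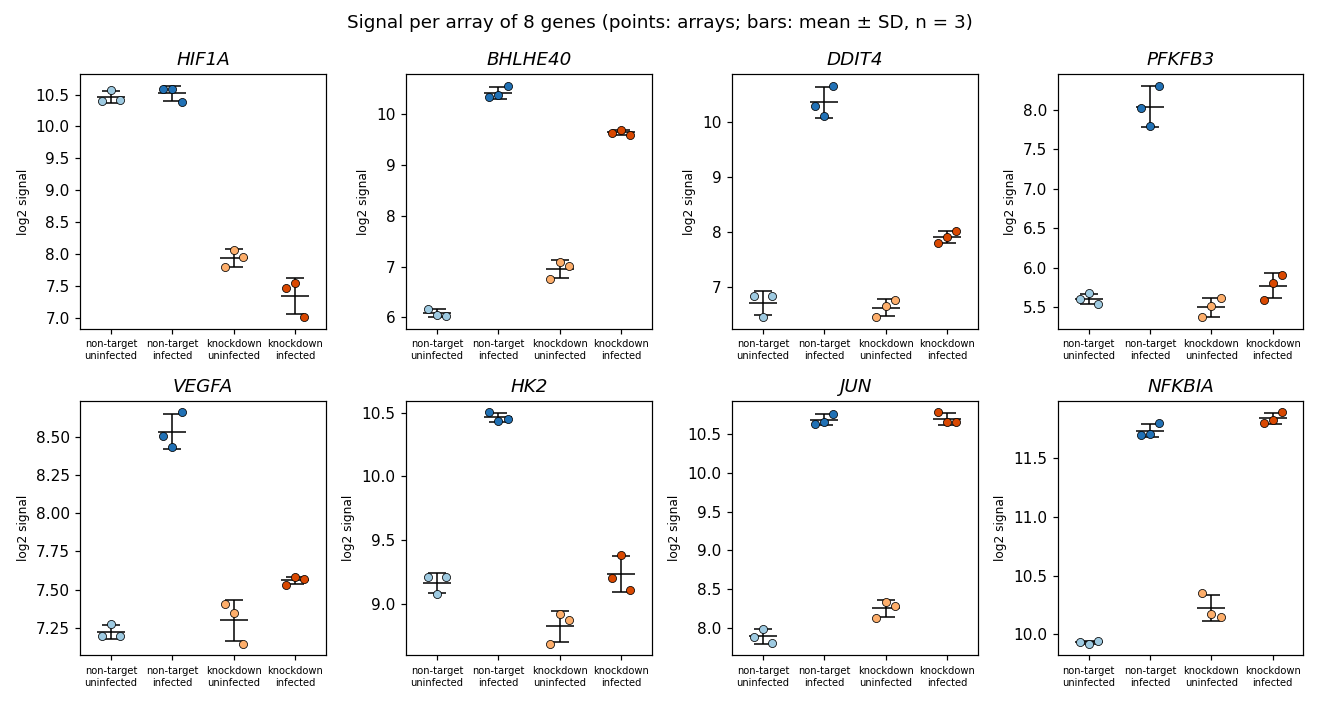
Log2 signal (vertical axis) of 8 genes on each of the 12 arrays, by group (horizontal axis); points are arrays and bars are the mean ± SD of 3 arrays, with a separate vertical scale for each gene that does not start at 0. HIF1A lies between 7.01 and 8.07 in the knockdown arrays and between 10.39 and 10.59 in the non-target arrays, and PFKFB3 rose by 2.43 on the log2 scale after infection of non-target cells against a change of 0.27 in knockdown cells.

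Infection of non-target cells raised genes of hypoxia signalling, glycolysis, inflammation and the immediate early response. BHLHE40, a transcriptional repressor and known HIF-1 target, rose 20.4-fold (4.35 ± 0.10, adjusted p = 7.2e-14). DDIT4, an inhibitor of mTORC1 signalling, rose 12.5-fold (3.65 ± 0.14, adjusted p = 6e-11). JUN, a subunit of the AP-1 transcription factor, rose 6.93-fold (2.79 ± 0.09), and TNFAIP3, an inhibitor of NF-kB signalling, rose 5.50-fold (2.46 ± 0.11). The deepest fall was that of the small nucleolar RNA SNORD14E, by 8.08-fold (-3.01 ± 0.28, adjusted p = 4.9e-06).

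Of 34 measured HIF-1 target genes outside glycolysis, 21 rose and none fell (31 and 0 adjusted over the list alone). Their mean log2 change was 0.89 (camera adjusted p = 5.9e-46, and adjusted p = 4e-04 with an estimated correlation). Besides BHLHE40 and DDIT4, ADM, the vasodilator peptide adrenomedullin, rose by 2.40 ± 0.09. Of 20 genes of glycolysis and glucose uptake, 7 rose and none fell (13 and 0 adjusted over the list alone; camera adjusted p = 1.1e-17). They included PFKFB3 (2.43 ± 0.12) and PFKFB4 (1.91 ± 0.12), bifunctional enzymes that set the level of an activator of glycolysis, and PDK1 (1.30 ± 0.11), a kinase that restrains pyruvate dehydrogenase. Among 12 components of the HIF pathway, EGLN3 (1.29 ± 0.18), CITED2 (0.93 ± 0.08) and EGLN1 (0.44 ± 0.08) rose and none fell, also adjusted over the list alone (camera adjusted p = 8e-04, and adjusted p = 0.079 with an estimated correlation). EGLN1 and EGLN3 encode HIF prolyl hydroxylases. EGLN1, EGLN3 and CITED2 also belong to the list of HIF-1 target genes outside glycolysis, so the calls of these lists are not separate.

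Inflammatory and immediate early genes also moved upwards. Of 35 genes of NF-kB signalling and inflammation, 12 rose and none fell (14 and 0 adjusted over the list alone; camera adjusted p = 1.2e-15), among them TNFAIP3, NFKBIA (3.48-fold), which encodes an NF-kB inhibitor, and IER3 (1.60 ± 0.10). Of 33 immediate early genes, 15 rose and 1 fell (19 and 2 adjusted over the list alone; camera adjusted p = 1e-21), led by JUN, the MAP kinase phosphatase DUSP1 (2.61 ± 0.09) and EGR1 (1.83 ± 0.13). The largest rises outside these lists were those of HCAR3 (2.27 ± 0.13), a hydroxycarboxylic acid receptor, ARRDC3 (2.03 ± 0.14) and NEDD9 (1.97 ± 0.08). Of 7 aryl hydrocarbon receptor targets, CYP1A1 (1.49 ± 0.12) and TIPARP (0.63 ± 0.12) rose (2 and 0 adjusted over the list alone; camera adjusted p = 0.017, and adjusted p = 0.13 with an estimated correlation).

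Falls were fewer. Of 16 heat shock genes, 4 fell and none rose (7 and 0 adjusted over the list alone; camera adjusted p = 5.3e-06), including the chaperone genes DNAJB1 (-0.72 ± 0.08) and HSPA8 (-0.46 ± 0.07) and CHORDC1 (-0.50 ± 0.08). Of 22 genes of sterol and fatty acid synthesis, 5 fell and none rose (7 and 0 adjusted over the list alone; camera adjusted p = 0.0038), including STARD4 (-0.64 ± 0.15), HMGCS1 (-0.59 ± 0.11) and IDI1 (-0.50 ± 0.11). Noncoding genes made up most of the deepest falls: SNORD14C (-1.62 ± 0.14), MIR17HG (-1.59 ± 0.15), SNORA75 (-1.39 ± 0.22), MIR15A (-1.22 ± 0.11), SNORD53 (-1.15 ± 0.17), SNORD75 (-1.12 ± 0.18) and SNORD30 (-1.07 ± 0.26). EIF5, a translation initiation factor gene, fell by 1.44 on the log2 scale. The probe sets of MPLKIP disagreed, with changes of -1.25, -1.17 and -0.23.

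In iron handling HAMP, the gene of hepcidin, rose (1.17 ± 0.11), TFRC rose (0.52 ± 0.13) and SLC40A1, the iron exporter, fell (-0.52 ± 0.11) among 14 genes (3 and 1 adjusted over the list alone; camera adjusted p = 0.040, and adjusted p = 0.10 with an estimated correlation). The camera call of this list was also lost without non-target infected replicate 1 (adjusted p = 0.092) and in 2 more of the fits without a single array, with quantile normalization (adjusted p = 0.060) and in the brighter part of the probe sets (adjusted p = 0.11). Of 27 hepatocyte genes FOXA2 (0.56 ± 0.10), NR0B2 (0.45 ± 0.10) and CYP27A1 (0.38 ± 0.09) rose (camera adjusted p = 0.0074, and adjusted p = 0.21 with an estimated correlation); 4 rose and 1 fell adjusted over the list alone. That list's call was lost without non-target uninfected replicate 2 (adjusted p = 0.087). Of 27 genes of the unfolded protein response, 2 rose and 2 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.70), with PPP1R15A (1.34 ± 0.12) and VEGFA (1.32 ± 0.09) higher and HERPUD1 (-0.65 ± 0.09) lower. In the list of extracellular matrix and coagulation, CCN1 (1.65 ± 0.09) and F3 (0.38 ± 0.08) rose and CCN2 fell (-0.42 ± 0.08) among 22 (4 and 1 adjusted over the list alone; camera adjusted p = 0.10). Among 19 p53 and apoptosis genes GADD45B (0.92 ± 0.10), GADD45A (0.48 ± 0.09) and MCL1 (0.41 ± 0.08) rose (5 and 4 adjusted over the list alone; camera adjusted p = 0.70). No list of other cell types passed the threshold, and of their 34 measured members only SOX9 was called.

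In total 477 of 18417 genes passed the threshold in non-target cells, 370 higher and 107 lower, and 73 of them changed at least 2-fold. With median centring of the arrays the count was 899, with 831 higher and 68 lower. Quantile normalization gave 469, with 356 higher and 113 lower. The balance of rises and falls thus depends on the scaling, and moved little with quantile normalization. All called genes of the 4 comparisons of 2 groups had no overlap between the groups, which chance gives for 10% of unselected genes. The calls were made on these same arrays, so the lack of overlap adds no support to them. The count was 738 without knockdown uninfected replicate 1, 305, 307, 304 and 311 without non-target uninfected replicates 1 and 2 and non-target infected replicates 1 and 3, and 1087 without both arrays that stood apart. Calls of 8 named genes were lost when a single array was left out: TFRC (highest adjusted p = 0.16, without non-target uninfected replicate 1), NR0B2 (0.14), CYP27A1 (0.19), IDI1 (0.091) and SLC40A1 (0.086) without non-target uninfected replicate 2, F3 (0.10) without non-target infected replicate 1, and STARD4 (0.16) and SNORD30 (0.13) without non-target infected replicate 3.

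In the knockdown line infection raised many inflammatory and immediate early genes, and fewer HIF-1 target genes passed the threshold. BHLHE40 rose 6.47-fold (2.69 ± 0.10, adjusted p = 6.4e-11), HCAR3 rose by the next largest amount (2.63 ± 0.13) and JUN rose 5.44-fold (2.44 ± 0.09). CXCL8, the gene of the neutrophil chemoattractant interleukin-8, rose 3.28-fold (1.71 ± 0.10, adjusted p = 1.9e-08). The deepest fall was again that of SNORD14E (-1.71 ± 0.28, adjusted p = 0.0029).

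Of the 35 genes of NF-kB signalling and inflammation, 11 rose and none fell (13 and 0 adjusted over the list alone; camera adjusted p = 1.5e-14), including TNFAIP3 (2.07 ± 0.11) and NFKBIA (1.61 ± 0.08). Of the 33 immediate early genes 14 rose and none fell (17 and 0 adjusted over the list alone; camera adjusted p = 1.3e-28), including DUSP1 (2.27 ± 0.09), CCN1 (1.89 ± 0.09) and EGR1 (1.89 ± 0.13). Other large rises were those of ARRDC3 (2.21 ± 0.14) and NEDD9 (1.76 ± 0.08). Of the 34 HIF-1 target genes outside glycolysis 8 rose and none fell (10 and 0 adjusted over the list alone), with ADM at 1.99 ± 0.09 and DDIT4 at 1.29 ± 0.14. Camera gave adjusted p = 1.5e-14 for that list, and adjusted p = 0.015 with an estimated correlation. Of the 20 genes of glycolysis and glucose uptake only HK2 was called (0.41; 3 and 0 adjusted over the list alone; camera adjusted p = 0.14). Of the aryl hydrocarbon receptor targets CYP1A1 (0.99 ± 0.12) and TIPARP (0.78 ± 0.12) rose (3 and 0 adjusted over the list alone; camera adjusted p = 0.0022, and adjusted p = 0.075 with an estimated correlation).

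Heat shock genes fell here too, with 3 of 16 called lower and none higher (5 and 0 adjusted over the list alone; camera adjusted p = 8.7e-05): DNAJB1 (-0.60 ± 0.08), CHORDC1 (-0.44 ± 0.08) and HSPA8 (-0.44 ± 0.07). Of the 22 genes of sterol and fatty acid synthesis 1 fell (3 and 0 adjusted over the list alone; camera adjusted p = 8.7e-05). HAMP rose (1.31 ± 0.11), as did CITED2 (1.02 ± 0.08), PPP1R15A (1.36 ± 0.12), GADD45B (0.95 ± 0.10), GADD45A (0.65 ± 0.09) and F3 (0.59 ± 0.08). HERPUD1 (-0.46 ± 0.09), DNAJB9 (-0.57 ± 0.12) and SLC40A1 (-0.50 ± 0.11) fell. As in non-target cells, deep falls were those of EIF5 (-1.41), SNORA75 (-1.49), SNORD30 (-1.40), SNORD14C (-1.37), MIR17HG (-1.28) and SNORD75 (-1.21). The pseudogene MTND2P28 (-1.17) and SNORD1A (-1.01) also fell, with -0.58 (adjusted p = 0.18) and -0.63 (adjusted p = 0.15) in non-target cells. The MPLKIP probe sets again disagreed (-1.51, -1.54 and 0.11). No list of other cell types passed the threshold.

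In total 271 genes passed the threshold in the knockdown line, 209 higher and 62 lower, and 51 of them changed at least 2-fold. The count was 219 without both arrays that stood apart and 142 from a fit on the 6 arrays compared. Without a single array the calls of HERPUD1 (highest adjusted p = 0.076), DNAJB9 (0.097) and SLC40A1 (0.15) were lost, each most clearly without knockdown uninfected replicate 2, and that of SNORD1A (0.072) without knockdown uninfected replicate 1. MTND2P28 was not called without both arrays that stood apart (-0.84, adjusted p = 0.059). On the 6 arrays compared the calls of SNORD14E (adjusted p = 0.059) and SNORD30 (adjusted p = 0.11) were lost, that of SNORD30 also with a trended and robust variance (adjusted p = 0.053) and when all probe sets were tested (adjusted p = 0.0504).

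The responses of the lines differed for 15 genes, 14 of them with a smaller response in the knockdown line. DDIT4 rose by 3.65 in non-target and 1.29 in knockdown cells, a difference of -2.36 ± 0.19 (5.13-fold, adjusted p = 1.2e-05). PFKFB3 rose by 2.43 in non-target cells against a change of 0.27 (adjusted p = 0.41) in knockdown cells, a difference of -2.16 ± 0.17 (adjusted p = 1.2e-05). BHLHE40 differed by -1.66 ± 0.14 (adjusted p = 1.2e-05) and PFKFB4 by -1.75 ± 0.16 (adjusted p = 5.5e-05).

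Of the 34 HIF-1 target genes outside glycolysis 6 had a smaller response in the knockdown line and none a larger one (15 and 0 adjusted over the list alone), with a mean difference of -0.51 (camera adjusted p = 2e-26). Besides DDIT4 and BHLHE40 they were PPP1R3C (-1.31 ± 0.16), a regulatory subunit that directs a phosphatase to glycogen, POFUT4 (-1.11 ± 0.15), the histone demethylase gene KDM3A (-1.08 ± 0.14) and VEGFA (-1.06 ± 0.12), an angiogenic growth factor gene. Of the 20 genes of glycolysis and glucose uptake 4 had a smaller response and none a larger one (9 and 0 adjusted over the list alone), with a mean difference of -0.47 (camera adjusted p = 1.1e-16). These were PFKFB3, PFKFB4, the hexokinase gene HK2 (-0.89 ± 0.13) and the enolase gene ENO2 (-0.76). ANKZF1, outside these lists, differed by -1.10 ± 0.15 (adjusted p = 0.057 when all probe sets were tested). With an estimated correlation both HIF-1 target lists held their calls (adjusted p = 0.0055 and adjusted p = 0.0012).

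No gene of NF-kB signalling and no immediate early gene was called by limma for a difference of responses (0 and 0 adjusted over each list alone). An unadjusted p under 0.05 was found for 7 of 35 and 7 of 33, against 1480 of all 18417 genes. Camera gave adjusted p = 0.53 and adjusted p = 0.87 for these lists. The mean response of the 67 genes of both lists in knockdown cells was 0.970 of that in non-target cells (95% interval 0.884 to 1.06), against 0.350 (0.238 to 0.461) for the 54 genes of both HIF-1 target lists. The 26 genes of mitochondrial oxidative phosphorylation had a mean difference of 0.13 with no member called (0 and 0 adjusted over the list alone, 5 with an unadjusted p under 0.05; camera adjusted p = 0.025, and adjusted p = 0.53 with an estimated correlation). That call was lost in 5 of the fits without a single array, with the highest adjusted p of 0.12 without non-target uninfected replicate 3. OR3A3, an olfactory receptor gene with low signal, was the only gene with a positive difference (0.82 ± 0.14, adjusted p = 0.027), and its call was lost in 9 of the fits without a single array. The count was also 15, with 12 of the genes shared, without both arrays that stood apart.

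**Figure D2:**
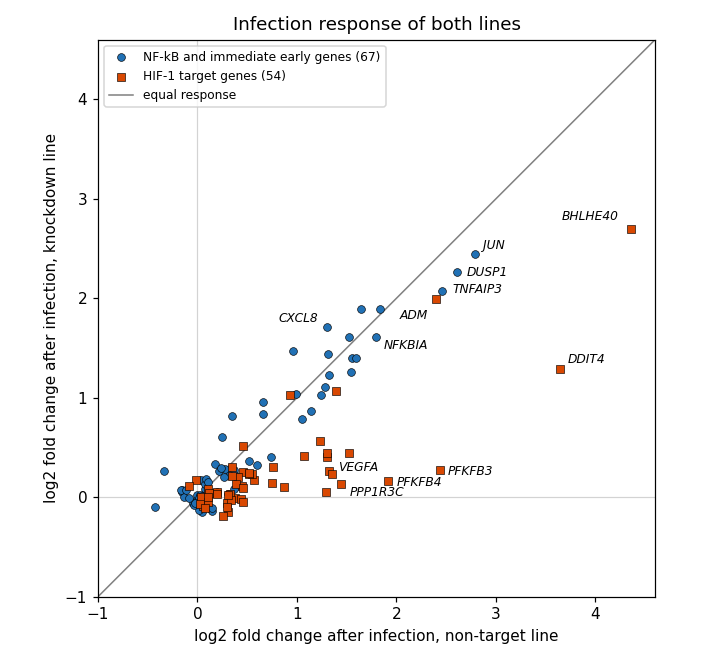
Log2 fold change after infection in the non-target line (horizontal axis) and in the knockdown line (vertical axis) for 54 HIF-1 target genes and 67 NF-kB and immediate early genes; points are genes and the grey line marks an equal response. DDIT4 (3.65 and 1.29) and PFKFB3 (2.43 and 0.27) lie below the line, and CXCL8 (1.30 and 1.71) lies above it.

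In uninfected cells the knockdown line differed from the non-target line in other genes besides HIF1A. SLC6A14, an amino acid transporter gene, was 4.13-fold higher (2.05 ± 0.20, adjusted p = 4.5e-05) and DPP4, a cell-surface peptidase gene, 2.79-fold higher (1.48 ± 0.12, adjusted p = 8.4e-06). VCAN, the gene of the proteoglycan versican, was 2.84-fold lower (-1.51 ± 0.11, adjusted p = 2.7e-06). BHLHE40 was 1.83-fold higher (0.87 ± 0.10, adjusted p = 1.3e-04).

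Other large positive differences were those of TSPAN7 (1.51 ± 0.10), UGT2B4 (1.39 ± 0.19), IL18 (1.20 ± 0.12), CRYBG3 (1.18 ± 0.15), TACC1 (2.15-fold), HSD17B2 (1.09 ± 0.13) and SULT1C2 (1.07 ± 0.13). SLCO4C1 was higher by 1.51 ± 0.16, while its dimmer second probe set gave 0.28. Lower genes included RBP7 (-1.32 ± 0.16), KLHL13 (-1.27 ± 0.11), CPED1 (-1.18 ± 0.13), TNIK (-1.06 ± 0.12), ZNF804A (-0.99 ± 0.12), CD24 (-0.94 ± 0.09), PCDHB14 (-0.91 ± 0.17) and CPN1 (-0.87 ± 0.11).

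Of the 20 genes of glycolysis and glucose uptake 3 were lower and none higher (8 and 0 adjusted over the list alone): PDK1 (-0.79 ± 0.11), ALDOC (-0.73 ± 0.09) and PFKP (-0.46 ± 0.10). Camera gave adjusted p = 6.6e-05 for this list, and adjusted p = 0.064 with an estimated correlation. Of the 34 other HIF-1 target genes 5 were lower and 1, BHLHE40, was higher (8 and 4 adjusted over the list alone), with TMEM45A (-0.82 ± 0.13) and the mitophagy receptor gene BNIP3L (-0.69 ± 0.12, adjusted p = 0.054 on the 6 arrays compared) among the lower. Camera gave adjusted p = 0.025 for that list, adjusted p = 0.36 with an estimated correlation, and adjusted p = 0.13 without knockdown uninfected replicate 1. Of 21 acute phase proteins 4 were higher and none lower (6 and 1 adjusted over the list alone; camera adjusted p = 0.0014, and adjusted p = 0.12 with an estimated correlation), including the heme-binding hemopexin gene HPX (0.71 ± 0.10), HP (0.56 ± 0.10) and FGB (0.53 ± 0.10). Of 27 hepatocyte genes NR0B2 (0.50 ± 0.10) and TTR (0.49 ± 0.10) were higher (7 and 0 adjusted over the list alone; camera adjusted p = 3.7e-04, and adjusted p = 0.15 with an estimated correlation).

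The camera calls of 3 further lists were lost with an estimated correlation: immediate early genes (2 of 33 higher, also adjusted over the list alone, adjusted p = 0.031, then adjusted p = 0.15), cell cycle genes (0 of 28 called, also adjusted over the list alone, with 3 at an unadjusted p under 0.05, adjusted p = 0.029, then adjusted p = 0.15) and iron handling (1 of 14 higher and 1 lower, 5 and 1 adjusted over the list alone, adjusted p = 0.022, then adjusted p = 0.12). Those of immediate early genes and cell cycle genes were also lost without a single array, with the highest adjusted p of 0.082 without knockdown uninfected replicate 2 and 0.18 without non-target uninfected replicate 3. Further called list members were CCN1 (0.50 ± 0.09), JUN (0.36 ± 0.09), THBS1 (0.52 ± 0.11), ABCC3 (0.65 ± 0.12), CASP1 (0.53 ± 0.13) and TLR2 (0.40 ± 0.09), which were higher, and AKR1B10 (-0.76 ± 0.10), ELOVL6 (-0.57 ± 0.11), SLC40A1 (-0.47 ± 0.11) and FADS2 (-0.47 ± 0.09), which were lower. Among markers of other cell types the epithelial gene CDH1 was higher (0.48 ± 0.09) and SPP1 lower (-0.43 ± 0.08), and PECAM1 was higher (0.55 ± 0.10). No list of other cell types passed the threshold.

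In total 319 genes differed in uninfected cells, 139 higher and 180 lower in the knockdown line, and 17 of them at least 2-fold. The lower genes outnumbered the higher ones only with some arrays: without knockdown uninfected replicate 1 there were 127 higher and 99 lower, and without both arrays that stood apart 149 higher and 129 lower (278 in total). Without non-target uninfected replicates 1, 2 and 3 there were 80, 75 and 74 higher and 73, 73 and 105 lower (153, 148 and 179 in total). The count was 160 on the 6 arrays compared and 139 when all probe sets were tested. The calls of ABCC3, HP, CASP1, FGB, THBS1, NR0B2, TTR, CDH1, TLR2, JUN, PFKP, FADS2, SLC40A1, ELOVL6 and PCDHB14 were lost when a single array was left out, with highest adjusted p-values from 0.053 for HP to 0.23 for CASP1, both without non-target uninfected replicate 1.

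In infected cells HIF-1 target genes and genes of glycolysis were lower in the knockdown line. DDIT4 was 5.47-fold lower (-2.45 ± 0.14, adjusted p = 3.2e-08), PFKFB3 4.82-fold (-2.27 ± 0.12, adjusted p = 2.2e-08), PFKFB4 4.17-fold (-2.06 ± 0.12) and PDK1 3.13-fold (-1.65 ± 0.11). SLC6A14 (2.12 ± 0.20), DPP4 (1.71 ± 0.12) and TSPAN7 (1.45 ± 0.10) were higher, as in uninfected cells. HP, the gene of the haemoglobin-binding haptoglobin, was 2.01-fold higher (1.01 ± 0.10, adjusted p = 2.2e-05).

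Of the 20 genes of glycolysis and glucose uptake 10 were lower and none higher (17 and 0 adjusted over the list alone), with a mean difference of -0.66 (camera adjusted p = 8.1e-28). Of the 34 other HIF-1 target genes 17 were lower and 1 higher (29 and 1 adjusted over the list alone), with a mean difference of -0.63 (camera adjusted p = 2.6e-36). POFUT4 (-1.55 ± 0.10), PPP1R3C (-1.42 ± 0.11), EGLN3 (-1.34 ± 0.18), BNIP3L (-1.30 ± 0.12) and HK2 (-1.23 ± 0.09) were among the deepest. Both lists held their calls with an estimated correlation (adjusted p = 1.7e-04 and adjusted p = 0.0018).

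Higher genes included SLCO4C1 (1.65 ± 0.16, its second probe set 0.03), UGT2B4 (1.44 ± 0.19), GSTA1 (1.37 ± 0.13), HSD17B2 (1.36 ± 0.13), SULT1C2 (1.21 ± 0.13), TACC1 (1.15 ± 0.09) and CRYBG3 (1.12 ± 0.15). Of 21 acute phase proteins 4 were higher and none lower (7 and 2 adjusted over the list alone; camera adjusted p = 0.0037, and adjusted p = 0.10 with an estimated correlation), with FGB at 0.88 ± 0.10 and ORM2 at 0.49 ± 0.12. Hepatocyte genes gave 3 higher of 27, CYP7A1 (0.93 ± 0.19), the rate-limiting enzyme of bile acid synthesis, TTR (0.53 ± 0.10) and AFP (0.39 ± 0.09), also 3 adjusted over the list alone, with camera adjusted p = 0.19. Camera calls of interferon-stimulated genes (1 of 30 higher, 2 higher and 1 lower adjusted over the list alone, adjusted p = 0.012), cell cycle genes (1 of 28 lower, 2 adjusted over the list alone, adjusted p = 0.012) and oxidative phosphorylation (2 of 26 higher, COX4I1 at 0.45 ± 0.08 and ATP5PO at 0.45 ± 0.11, 5 higher and 1 lower adjusted over the list alone, list adjusted p = 0.045) were lost with an estimated correlation (adjusted p = 0.10, adjusted p = 0.10 and adjusted p = 0.42). They were also lost without knockdown infected replicate 2 for interferon-stimulated genes (adjusted p = 0.066) and without knockdown infected replicate 3 for cell cycle genes (adjusted p = 0.065) and oxidative phosphorylation (adjusted p = 0.23).

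Other called list members were CCN1 (0.74 ± 0.09), ATF3 (0.61 ± 0.10), CCN2 (0.39 ± 0.08) and CITED2 (0.31 ± 0.08), which were higher, and AKR1B10 (-0.56 ± 0.10), ABCC2 (-0.53 ± 0.12), FADS2 (-0.49 ± 0.09), KLF10 (-0.45 ± 0.09), ELOVL6 (-0.43 ± 0.11) and SRXN1 (-0.39 ± 0.09), which were lower. Of the epithelial markers CDH1 (0.53 ± 0.09) and EPCAM (0.40 ± 0.09, its second probe set 0.18) were higher, and of 13 fibroblast, stellate and endothelial markers PECAM1 was higher (0.74 ± 0.10). No list of other cell types passed the threshold.

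In total 490 genes differed in infected cells, 202 higher and 288 lower, and 35 of them at least 2-fold. With median centring 157 were higher and 364 lower, and with quantile normalization 214 and 237. The count was 752 without knockdown uninfected replicate 1, 250 and 296 without knockdown infected replicates 1 and 3, 236, 282 and 276 without non-target infected replicates 1, 2 and 3, 490 without both arrays that stood apart, and 240 when all probe sets were tested. The calls of CYP7A1, ORM2, ATP5PO, EPCAM, CCN2, AFP, CITED2, SRXN1, ELOVL6, KLF10 and ABCC2 were lost when a single array was left out, with highest adjusted p-values from 0.053 for KLF10, without non-target infected replicate 1, to 0.18 for ORM2, without knockdown infected replicate 3.

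The infection responses of both lines were compared across genes, which are not independent replicates. The log2 changes of 18417 genes had a Pearson correlation of 0.509 and a Spearman correlation of 0.233, and these comparisons share no array. Called rises overlapped in 151 genes (370 and 209 called, 4.20 expected from independent lists) and called falls in 34 (107 and 62 called, 0.360 expected). No gene was called in opposite directions. For knockdown against non-target cells 79 genes were higher in both infection states (139 and 202 called, 1.52 expected) and 89 lower (180 and 288 called, 2.81 expected). Lists of pattern recognition receptors, the unfolded protein response, NRF2 targets, metallothioneins, p53 targets and extracellular matrix did not pass the camera threshold in any comparison. BHLHE40 was the only gene called in opposite directions, 0.87 in uninfected and -0.78 in infected cells.

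**Figure D3:**
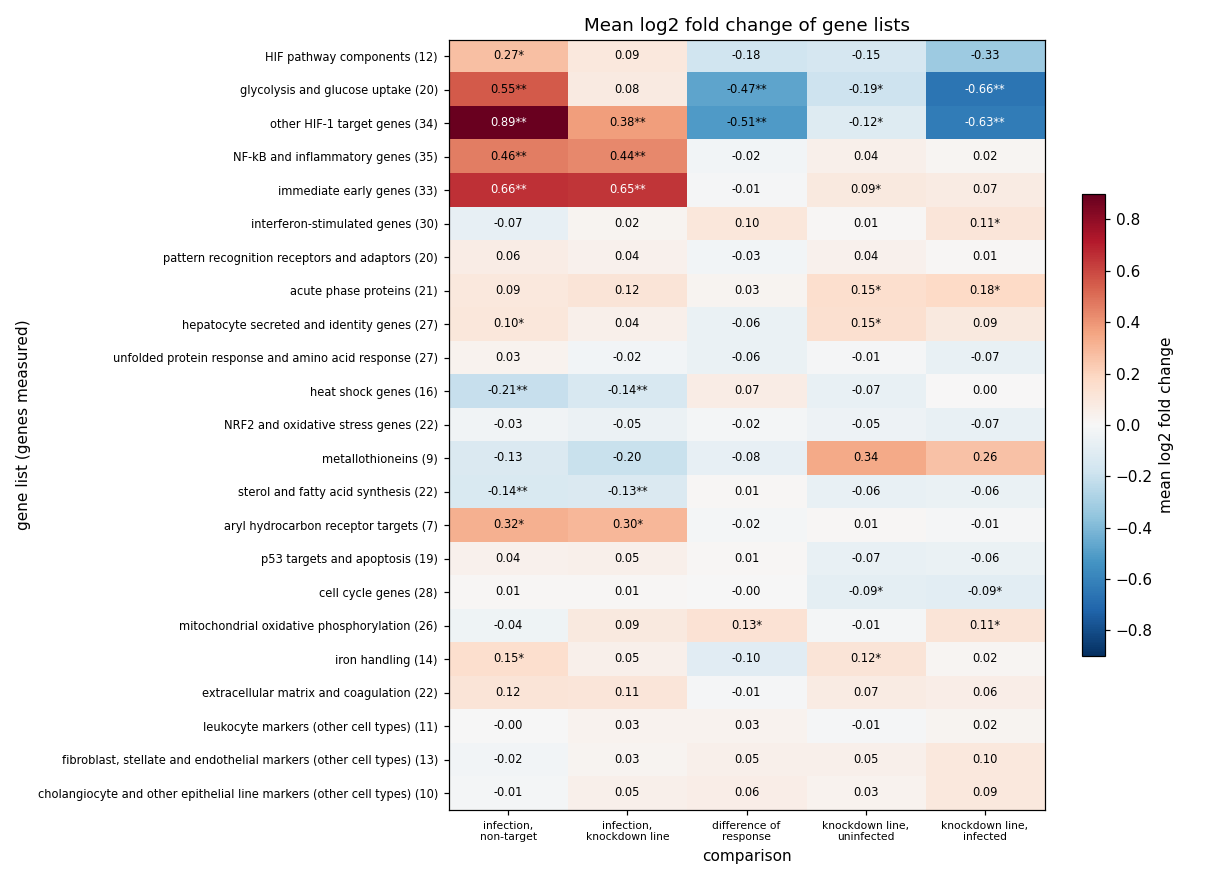
Mean log2 fold change of 23 gene lists (rows, with the number of genes measured) in 5 comparisons (columns), as colour and number. A single star marks camera adjusted p under 0.05 and a pair of stars marks that this also held with an estimated correlation; the mean of glycolysis and glucose uptake was 0.55 after infection of non-target cells, 0.08 in knockdown cells and -0.47 for the difference.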

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

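The tests of the HIF-1 target pattern below were chosen after the result was seen, while those that regroup the arrays were planned. The infection response differed between the lines by the test of the difference itself for 15 genes. The log2 differences, knockdown minus non-target, were -2.36 for DDIT4, -2.16 for PFKFB3, -1.75 for PFKFB4, -1.66 for BHLHE40, -1.31 for PPP1R3C, -1.11 for POFUT4, -1.10 for ANKZF1, -1.08 for KDM3A, -1.06 for VEGFA, -0.89 for HK2, -0.87 for HILPDA, -0.76 for ENO2, -0.70 for PNRC1, -0.66 for PLIN2 and 0.82 for OR3A3. The mean difference was -0.47 for glycolysis and glucose uptake, -0.51 for the other HIF-1 target genes and 0.13 for mitochondrial oxidative phosphorylation. HILPDA and PLIN2, which encode lipid droplet proteins, and PNRC1 are outside the naming rule and are given because they complete the count.

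HIF-1 target genes had a smaller response in the knockdown line. A generally weaker response of those cells is argued against as the cause by the NF-kB and immediate early genes as a set. Their mean response was 0.970 of that in non-target cells (95% interval 0.884 to 1.06). Single members moved both ways, such as JUN (2.79 in non-target and 2.44 in knockdown cells) and CXCL8 (1.30 and 1.71). Bacterial load is not given in the sources used here, so a lower load that the mean of this set did not reflect stays open. The smaller response of the target genes did not rest on knockdown infected replicate 3, without which the mean difference of the 54 target genes was -0.48 (-0.61 to -0.36). A higher starting level in uninfected knockdown cells is argued against for these genes as a set, which had a mean difference of -0.14 there (-0.22 to -0.06) although 13 of the 54 were higher. For BHLHE40 a higher start is part of the difference of responses of -1.66 by construction. It started 0.87 higher (0.67 to 1.08) in knockdown cells and differed by -0.78 after infection. The loss of HIF1A may account for the pattern, but it cannot be told apart from other differences between the lines, of which 318 genes besides HIF1A were called before infection and which come from a single line per state.

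With other groupings of the 12 arrays, within each line, 5 of 100 splits (the real one and others drawn at random) called at least as many genes for the difference of responses as the real 15, and the others called 411, 61, 36 and 33, so chance is not excluded by this count. The 4 other splits kept the non-target arrays as labelled and had 1 truly infected array among the 3 treated as infected in the knockdown line, a description made after these splits were seen. By construction the infection response shared by the lines does not cancel in such splits, so their counts do not measure what chance gives for the 15 genes. Splits with 2 truly infected arrays there called 12 to 14 genes, and those with mixed non-target arrays at most 1, but mixing infected and uninfected arrays in a group also widens its spread. These splits therefore neither exclude chance nor speak for it. For the other comparisons the 6 arrays allow 10 splits, too few for a share under 0.05. In each, 1 split, the real one, called as many genes: 477 against at most 1 for infection of non-target cells, 271 against 0 for knockdown cells, 319 against 0 for uninfected cells of both lines, and 490 against at most 2 for infected cells.

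Probe sets outside the gene-level comparisons also changed with infection. Of those with several gene symbols 50 were called in non-target and 23 in knockdown cells, and of those with no gene symbol 174 and 127, of which 138 and 106 were lower.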

How the results depend on the processing

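The fit without both arrays that stood apart and the lists without older symbols were added after seeing the data. HIF1A stayed lower under every alternative run, from -2.59 to -2.45 over fits without a single array (highest adjusted p = 7.6e-07). Of the named gene results 139 kept their state, called or not called, under every alternative run on them, and 45 lost a call in at least 1. Of the list results 15 held and 17 did not. The stricter thresholds were applied only to the counts of genes and are not part of these totals. None reversed. All 17 lists that lost a call did so with an estimated correlation, and 3 of them with fry. Pseudocounts were not run, since the values are on a log scale. Counts are given in the order infection of non-target cells, infection of knockdown cells, difference of responses, lines uninfected and lines infected. Array weights gave 967, 714, 30, 572 and 1366. At least 2-fold gave 73, 51, 9, 17 and 35, and adjusted p 0.01 gave 243, 155, 11, 121 and 172, by construction. Median centring gave 899 for infection of non-target cells. The infected arrays had the lower medians, and centring moved the median change of all genes there from -0.005 to 0.060. Fits on the 6 arrays compared gave 658 for infection of non-target cells, 142 for knockdown cells, 160 for uninfected and 375 for infected lines. By construction these fits leave the group differences unchanged (HIF1A -2.52 in both fits of uninfected lines). Only the estimate of the spread, and the number of arrays behind it, can have moved these counts. Testing all probe sets gave 139 and 240 genes for uninfected and infected lines, with more tests. Without both arrays that stood apart, infection of non-target cells gave 1087, which held all 477 genes. Neither array belongs to that comparison, so there too only the estimate of the spread, and the number of arrays behind it, differed. Without a single array the counts ran from 304 to 738, 187 to 259, 11 to 18, 148 to 411 and 236 to 752. The correlation of the responses of both lines was 0.577 in the brighter part of the probe sets, 0.559 without both arrays and 0.423 to 0.569 without a single array; the cause was not tested. Whether the replicate numbers pair the samples was not settled. Of 18 same-number pairs 7 had r over 0.1 (range -0.24 to 0.30), and 7 of 12 arrays correlated best with their own number. Pairs outside the knockdown uninfected group all had a positive r (0.001 to 0.30), while those with it ran from -0.24 to 0.19. The arrays that stood apart, which bear different numbers, had r = 0.30 with each other. With a replicate block the counts were 482, 281, 12, 329 and 522. Without older symbols the other HIF-1 target list had 33 members and a mean difference of responses of -0.49 (camera adjusted p = 2.8e-24, and adjusted p = 0.0062 with an estimated correlation), and oxidative phosphorylation had 25 members (camera adjusted p = 0.033 for the difference and adjusted p = 0.040 for infected lines); no list call changed. Genes near the olfactory receptor level are limited by signal over background.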

Other observations

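The tests of gene families and of the snoRNA pattern were chosen after the results were seen. Histone genes, which encode the proteins that package DNA, moved upwards after infection in both lines. Of 73 histone genes 20 were called higher in non-target and 22 in knockdown cells and none lower (28 and 38 higher and none lower adjusted over the family alone). Without a single array the higher counts ran from 12 (without non-target infected replicate 2) to 23 in non-target and from 14 (without knockdown infected replicate 3) to 23 in knockdown cells. They were 13 in non-target cells without non-target uninfected replicate 1 or 2 or non-target infected replicate 3. H2AC15 rose by 1.16 ± 0.14 and 1.29 ± 0.14, and H2BC9 by 0.83 ± 0.10 and 0.66 ± 0.10. The mean change of the family was 0.24 and 0.33 (camera adjusted p = 1.4e-11 and adjusted p = 5.3e-25, and adjusted p = 0.11 and adjusted p = 0.039 with an estimated correlation), and it was 0.25 and 0.34 under quantile normalization and 0.31 and 0.36 under median centring. Near-identical histone genes can share probes, so the values of single members are uncertain.

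Small nucleolar RNAs, which guide chemical modification of ribosomal RNA, moved downwards on average, with members in both directions. Of 175 genes 18 were called lower in non-target and 15 in knockdown cells and none higher over all genes. Adjusted over the family alone, 21 were lower and 5 higher in non-target cells and 34 lower and 2 higher in knockdown cells. The median change in non-target cells was -0.05, and 76 of the genes had a positive change there. Without non-target uninfected replicate 1 or 2, or non-target infected replicate 2 or 3, 11 were called lower in non-target cells. The family mean was -0.14 and -0.24 (camera adjusted p = 9.7e-04 and adjusted p = 7.6e-17, and adjusted p = 0.43 and adjusted p = 0.072 with an estimated correlation), and it was -0.12 and -0.24 under quantile normalization and -0.07 and -0.21 under median centring. The larger value in knockdown cells rested on knockdown infected replicate 3, without which the mean there was -0.12 (camera adjusted p = 8.4e-07) with 12 lower and 2 higher. SNORD14C and SNORD14E lie within HSPA8, which fell by 0.46 on the log2 scale in non-target cells.

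Over both lines the mean change of the 110 snoRNA genes above background was -0.24 (95% interval -0.45 to -0.03). It was not due to knockdown infected replicate 3 alone, without which it was -0.15 (-0.19 to -0.11) and, in knockdown cells, -0.13 in place of -0.31. A host gene was assigned to 57 of the snoRNA genes. With all arrays these 57 changed by a mean of -0.27 (-0.46 to -0.07), and their 43 host genes by 0.0072 (-0.015 to 0.029). For these 57 as a set, this argues against a lower level of host RNA as the cause. The other snoRNA genes, SNORD30 and SNORD75 among them, had no assigned host and were not covered. Lower recovery of short RNAs from infected cells may account for the lower snoRNA signal. The 55 microRNA and snRNA genes above background also fell over both lines, by a mean of -0.10 (-0.19 to -0.01). In each line alone the interval held 0 (-0.24 to 0.02 in non-target and -0.22 to 0.03 in knockdown cells). The 2 classes above background were not tested apart. With dim genes included, the 20 snRNA genes had median changes of 0.02 and -0.01, and the 173 microRNA genes -0.07 and -0.04. The fall of snoRNA genes beyond that of the 55 genes was -0.14 (-0.40 to 0.13), or -0.03 (-0.13 to 0.07) without knockdown infected replicate 3. The criterion of this last test was rewritten after a first run: it had compared with the snoRNA mean without its spread, and with that first criterion this explanation had been argued against. No biological explanation other than the RNA level of the assigned host genes was tested.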
